A study of Mus musculus with 2 samples.

How the data were processed

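Single cells of the mouse uterus at gestational day 3.5 were measured in 2 libraries, 1 from a control (floxed Mig-6 without Cre) and 1 labelled knockout (floxed Mig-6 with Cre under the progesterone receptor gene, Pgr). Mig-6 is the protein of the gene Errfi1. Uteri were digested with trypsin, blood cells were removed with a dead cell removal kit, and polyadenylated RNA was captured with 10x droplets, per the labels' protocols. The deposited matrices hold integer counts of unique molecular identifiers (UMIs) per gene and cell, made by the authors with Cell Ranger 7.0.1, per the file headers. Seurat, with no version, and the genome build mm39 are named per the submitters' processing notes. No cell annotation by the authors was used here. The reference available was GRCm38 with GENCODE M21, which is another build, so no coordinates were used and gene names were taken from the deposited feature tables of 32285 features.

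Barcodes were kept with at least 500 genes and at most 15% mitochondrial UMIs. The control had 4627 deposited barcodes, of which 65 were under the gene minimum and 126 over the mitochondrial limit. The library labelled knockout had 3118 barcodes, of which 115 were under the gene minimum and 114 over the limit. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, which took 159 control barcodes and 70 barcodes of the library labelled knockout. The kept cells numbered 4303 and 2881, with median UMI counts of 9184 and 4895.

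Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Epithelial cells were clustered again at resolution 0.5 to separate luminal from glandular cells. Clusters were named from 22 marker sets fixed before the data were examined, so a class name stands for cells like that type. The filters, gene lists, alternatives and the rule for named genes were also fixed before the data were examined. The scoring of clusters by their markers, the epithelial resolution and the conditions for a name were set after the clusters had been seen. A cluster of 40 shallow control cells, 0.930% of the control and 0 cells of the other library, stayed unnamed. Another 32 epithelial cells with stromal genes among their leading genes (14 control cells, 0.325%, and 18 cells labelled knockout, 0.625%) were left out of both epithelial classes. Classes with under 50 cells in either library were not compared gene by gene, apart from Errfi1 and Pgr. These were macrophage, endothelium, smooth muscle, pericyte, and B or plasma cells. Macrophages, endothelium, NK-like and plasma-like cells were also pooled as a background of cells. NK-like cells gave 624421 of 1680130 pooled UMIs in the control and 304180 of 636744 in the library labelled knockout. Pooled ratios can therefore mix makeup with expression. The NK-like class may include T cells or other innate lymphoid cells.

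UMIs were summed per class and library and scaled to the total of that class and library (CPM, the usual scale for UMI sums). Ratios of CPM carry exact conditional 95% intervals, single sums exact Poisson intervals, and shares of cells exact binomial intervals. These intervals cover counting error only. With 1 library per group there were no replicates, so no test was made and each difference is one between these libraries. A fold against a library at 0 was computed against a floor of 3 counts in that library. The median log2 ratio over genes with at least 100 UMIs was -0.13 in epithelium and -0.02 in stroma, and values were not recentred on it.

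The genes singled out by size were the 10 higher and 10 lower in epithelium and in stroma, and the 3 higher and 3 lower in each other class compared. They were ranked by the 95% bound of the ratio nearest 1, among genes with at least 50 CPM in the higher library and a ratio of at least 2. Mitochondrial, ribosomal and hemoglobin genes and unnamed gene models were left out of that ranking. Genes whose CPM was under 0.25 of their level in another class of the same library were left out too, since free RNA could supply them. Members of the gene lists were named with their own values. Near-identical families (Sprr2, Clca, Ifit and the H2 genes) and antisense or long noncoding genes (Far2os1, Far2os2, Kcnq1ot1 and Xist) can share reads, and their values are uncertain.

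The 21 gene lists covered the target and receptors, epithelial and stromal progesterone responses, the estrogen response, the cell cycle, ERK feedback, EGFR family ligands, the LIF and STAT3 axis, the WNT pathway, uterine glands, decidualization, extracellular matrix, junctions and polarity, interferon response, antigen presentation, chemokines and cytokines, dissociation stress, hypoxia and glycolysis, nuclear RNA, mitochondrial RNA and hemoglobin. A list was summarised by the median log2 ratio of members with at least 20 UMIs in the class. Its interval is the central 95% of medians over 1000 Poisson redraws of the counts. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Members were also counted as higher by 2-fold or more, lower by 2-fold or more, or within 2-fold. For hemoglobin, 0 members in epithelium and 1 in stroma reached the UMI minimum, so no median is given.

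Alternatives were a looser cell filter (200 genes, 25% mitochondrial UMIs), no removal of doublets, clustering each library alone, Leiden resolution 2, scaling by the median of ratios, means over cells, cells thinned to 2000 UMIs, subtraction of 10% free RNA, and other UMI minimums (1 and 100) for list members. Thinning left out 88 control cells and 362 cells labelled knockout that held fewer UMIs. Luminal or glandular cells alone, and clustering without 188 marker and gland genes, were added after the data had been seen.

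The calculations were tested on simulated counts with 200 genes set to known folds. These were Poisson draws of class sums, the model that the intervals assume, without variation between cells or animals. The coverage below therefore checks the calculation only. For epithelium, on 13284 genes, intervals covered 95.7% of true ratios. The direction was recovered there for 100% of 4-fold higher, 90.0% of 2-fold higher, 93.2% of 2-fold lower and 94.8% of 4-fold lower genes. For stroma, on 14392 genes, intervals covered 96.3%, and the recovered shares were 100%, 88.0%, 72.7% and 86.2% in the same order. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.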

Results

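Transcriptomes of single uterine cells were collected at gestational day 3.5, shortly before the embryo attaches, from 1 control mouse library and 1 library labelled knockout for Mig-6. Mig-6, the product of Errfi1, is a feedback inhibitor of the EGF receptor that progesterone induces in the uterus. The Cre named in the knockout label is driven from the progesterone receptor gene, so deletion is directed to cells that express it. The control library held 44871170 UMIs over 4627 barcodes, with a median of 9090 UMIs per barcode. The library labelled knockout held 23317904 UMIs over 3118 barcodes, with a median of 4695 UMIs. Class names below stand for clusters like that cell type, and levels are UMI sums per class in CPM.

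Errfi1 itself was compared first, since it checks the labels. In luminal-like epithelium its level was 541.6 CPM in the control and 517.1 CPM in the library labelled knockout, a ratio of 0.955 (0.922 to 0.989). In glandular-like epithelium Errfi1 was 826 CPM and 525 CPM, 1.58-fold lower (1.43 to 1.74). In stroma-like cells it was higher in the library labelled knockout, at 745 CPM against 194 CPM, a ratio of 3.85 (3.68 to 4.02). The background classes, which carry little Pgr, had ratios of 1.60 (1.05 to 2.44) in NK-like cells, 1.51 (0.870 to 2.53) in endothelium, 0.669 (0.272 to 1.44) in macrophages and 4.50 (1.47 to 16.3) in plasma-like cells, the last on 5 and 12 UMIs. Smooth muscle carried Pgr at 264 CPM in the control and 508 CPM in the library labelled knockout, and pericytes at 479 and 355 CPM. On these few cells, their Errfi1 ratios were 3.06 (2.17 to 4.29) and 2.84 (2.09 to 3.85). Errfi1 therefore went against the label in stroma, smooth muscle and pericytes. Every direction given here is between the library labelled knockout and the control library. Which part of the gene is removed is not given in the sources used here, and a 3' tag outside the deleted part checks nothing.

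**Figure D1:**
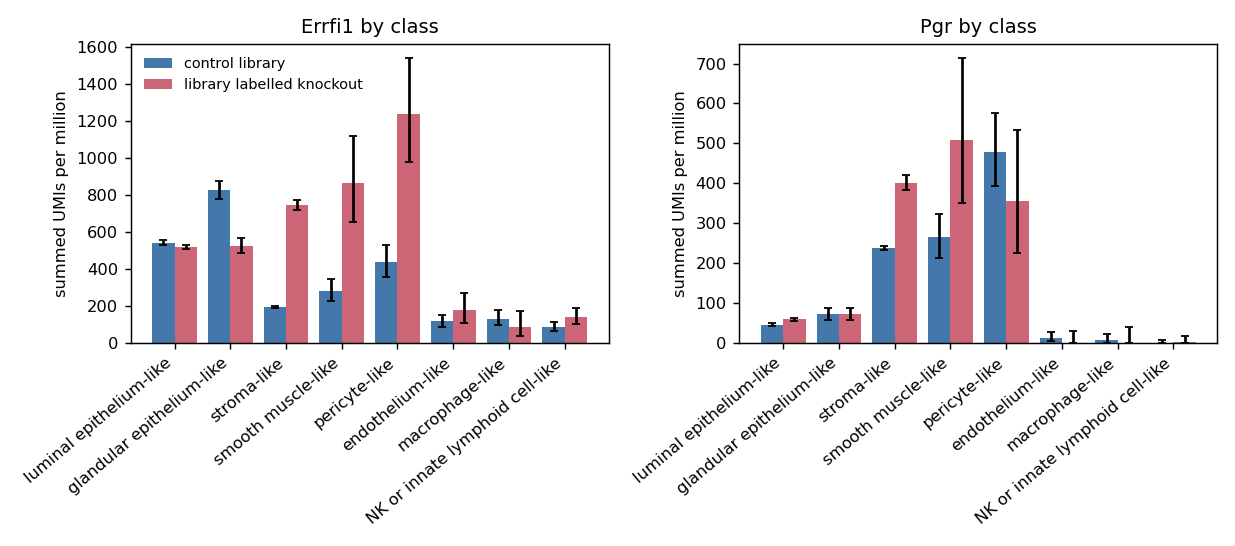
Levels of Errfi1 (left) and Pgr (right) as summed UMIs in CPM (vertical axes) per cell class (horizontal axes), as bars for the control library and the library labelled knockout with exact 95% Poisson intervals as error bars. In stroma the Errfi1 level was 194 CPM in the control and 745 CPM in the library labelled knockout, while in luminal epithelium the levels were 541.6 and 517.1 CPM.

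Receptors of the same pathways were present in both libraries. Pgr, the progesterone receptor, was 238 CPM in control stroma and 401 CPM in stroma of the library labelled knockout, 1.69-fold higher (1.60 to 1.78), and 48.8 and 59.6 CPM in epithelium. The library labelled knockout carries Cre at Pgr (Pgrcre/+) and the control does not. Any effect of Cre at Pgr is therefore not separated from Mig-6 deletion, and Pgr counts do not give the level of working receptor. Esr1, the estrogen receptor, was 568 and 482 CPM in epithelium and 597 and 789 CPM in stroma. Egfr, the EGF receptor, was 1.44-fold higher (1.34 to 1.54) in epithelium and 1.38-fold higher (1.30 to 1.47) in stroma. The target and receptor list had 0 of 6 measured members beyond 2-fold in epithelium (median log2 ratio 0.09) and 1 of 5, Errfi1, in stroma (median 0.47).

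The makeup of the cells addressed whether the library labelled knockout differs in its epithelial, stromal and immune compartments. Epithelium-like cells made up 16.6% of control cells (15.5 to 17.7) and 49.4% (47.5 to 51.2) in the library labelled knockout, a difference of 32.8 percentage points (30.6 to 34.9). Luminal-like cells were 14.0% and 44.1%, and glandular-like cells 2.58% and 5.24%. The luminal name rested on fewer markers in the library labelled knockout. Its luminal clusters, with 463, 256 and 551 of its cells, had 3, 3 and 5 luminal markers detected, where 3 was the minimum for a name. The control luminal clusters had 6 each. Calb1 and Wnt7a, given below as lower in epithelium, are among the luminal markers. Stroma-like cells were 74.1% (72.8 to 75.4) and 38.6% (36.8 to 40.4), a difference of -35.5 points (-37.7 to -33.2). Immune-like cells were 4.21% and 7.71%, a difference of 3.50 points (2.35 to 4.69), and the NK-like class within them was 2.32% and 5.66%. Macrophages were 1.39% in both libraries and endothelium 1.35% and 1.39%. Digestion and the kit used to remove blood cells can shift such shares too, which was not tested. The libraries also differed in depth, with median UMIs per stromal cell of 8952 and 3595. Clusters 0, 1, 2, 3, 5 and 7 held 98.8% of control stromal cells and clusters 13, 18 and 19 held 92.7% of those labelled knockout. Luminal cells split alike, with 96.5% of control cells in cluster 4 and 99.8% of those labelled knockout in clusters 8, 15 and 20.

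**Figure D2:**
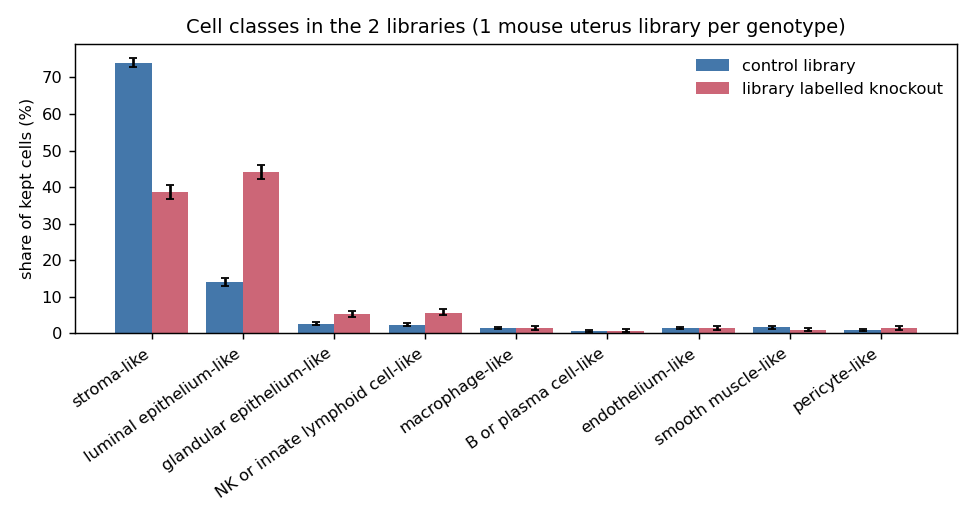
Share of kept cells in percent (vertical axis) per cell class (horizontal axis), as bars for both libraries, with exact binomial 95% intervals as error bars. Stroma was 74.1% of control cells and 38.6% of cells labelled knockout, and luminal epithelium 14.0% and 44.1%.

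In epithelium, the comparison asked whether progesterone and estrogen targets, proliferation and EGF receptor output differ between the control and the library labelled knockout. Progesterone targets were broadly lower in the library labelled knockout. The series' design gives n = 1 per genotype and the hormonal state of the animals is not given in the sources used here. The progesterone and estrogen lists therefore do not separate genotype, which joins Mig-6 deletion and Cre at Pgr, from hormonal state. Ihh, the epithelial ligand that signals to stroma under progesterone, was 34.4 CPM in the control and 1.11 CPM, 31.0-fold lower (19.5 to 52.0). Cyp26a1, which clears retinoic acid, was 25.3-fold lower (14.5 to 48.4), Hdc, which makes histamine, 20.4-fold lower (18.2 to 22.9), and Calb1, a calcium-binding protein, 19.1-fold lower (16.9 to 21.6). Areg, an EGF receptor ligand induced by progesterone, was 8.67 and 3.15 CPM, 2.75-fold lower (1.94 to 3.92). Of 17 measured members of the epithelial progesterone list, 12 were at least 2-fold lower, 1 was higher and 4 lay within 2-fold. The list's median log2 ratio was -2.39 (-2.69 to -2.06), below all 10000 matched random lists (percentile 0). In luminal cells alone the median over 16 members was -2.13, and in glandular cells alone it was -0.27 over 11 members. The epithelial progesterone response in glandular epithelium ranged from -0.50 by means over cells to -0.11 with each library clustered alone.

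Estrogen targets of the epithelium were higher in the library labelled knockout. Muc4, a membrane mucin, was 3.43 and 43.3 CPM, 12.6-fold higher (9.05 to 18.2). Lcn2, a secreted iron-siderophore binder, was 1553 and 5591 CPM, 3.60-fold higher (3.54 to 3.66), complement C3 3.36-fold higher (3.29 to 3.44), and Ltf, lactoferrin, 2.90-fold higher (2.82 to 2.98). Muc1, a mucin of the apical surface, was within 2-fold at 65.2 and 80.9 CPM. Of 17 measured estrogen list members, 7 were at least 2-fold higher and 0 lower, with a median of 0.84 (0.74 to 0.89) and percentile 100. In glandular cells alone the median was 2.23 over 13 members, with Ltf at 24.2 and 604 CPM, but the epithelial estrogen response in glandular epithelium was 0.78 with members of at least 100 UMIs and 1.08 with members of at least 1 UMI. The pooled NK-like, macrophage, endothelial and plasma-like cells had a median of 2.78 over 8 members, so these transcripts were also counted in cells that are not epithelial, and free RNA is not excluded as their source in glandular cells.

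Cell cycle genes were lower in epithelium of the library labelled knockout. Cdk1, the mitotic kinase, was 11.0 and 0.993 CPM, 11.1-fold lower (6.66 to 19.7), Top2a, a topoisomerase of dividing cells, 8.12-fold lower (5.97 to 11.2), and Mcm5, part of the replicative helicase, 7.41-fold lower (5.54 to 10.0). Mki67, a marker of proliferation, was 6.28 and 1.23 CPM, 5.12-fold lower (3.09 to 8.82). Of 26 list members, 21 were at least 2-fold lower, 0 higher and 5 within 2-fold, at a median of -2.21 (-2.38 to -1.93) and percentile 0. With cells thinned to 2000 UMIs the median was -1.44. In glandular cells alone, where 4 members were measured, it was 0.27 (-0.33 to 0.84).

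Feedback genes of ERK signalling were modestly higher in epithelium. Phlda1 was 235 and 819 CPM, 3.49-fold higher (3.35 to 3.65), Fosl1, an AP-1 subunit, 2.55-fold higher (2.12 to 3.07), and Dusp6, an ERK phosphatase, 1.82-fold higher (1.57 to 2.12). Of 15 measured ERK feedback members, 3 were at least 2-fold higher and 12 within 2-fold, at a median of 0.44 (0.37 to 0.74). Glandular cells alone had a median of -0.08 (-0.36 to 0.17) with no settled sign, as ERK feedback in glandular epithelium was -0.38 with members of at least 100 UMIs and 0.11 with at least 1 UMI.

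Gland genes were lower in glandular-like cells of the library labelled knockout. The serine protease Prss29 was 14067 and 2587 CPM, 5.44-fold lower (5.24 to 5.65), and its relative Prss28 was 5.81-fold lower (5.12 to 6.62). Foxa2, the transcription factor of gland development, was 67.3 and 29.7 CPM, 2.27-fold lower (1.53 to 3.43). Lif, the gland cytokine needed for implantation, was 3.30-fold lower there (1.47 to 8.38) on 28 and 8 UMIs, but over the whole epithelium it was 10.2 and 19.2 CPM. Of 10 measured gland list members, 6 were at least 2-fold lower and 4 within 2-fold in glandular cells, at a median of -1.45 (-1.78 to -0.97). The list shares genes with the markers that name these cells, and with clusters made without those genes the median was -1.52. Among genes singled out by size in glandular cells, Calca, the calcitonin gene, was 45.3-fold lower (12.2 to 379) on 2 UMIs in the library labelled knockout, and Gkn3 8.10-fold lower (5.50 to 12.3). Ltf was 24.9-fold, Lcn2 18.5-fold and Sprr2f 10.6-fold higher, all of them genes with still higher levels in luminal cells of that library.

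WNT genes were lower in epithelium too. Wnt11 was 19.6-fold lower (9.54 to 46.6), Wnt7a, a luminal WNT ligand, 10.7-fold lower (7.55 to 15.6), and Lgr5, a WNT-responsive receptor, 5.31-fold lower (4.59 to 6.16). The WNT list had 6 of 12 measured members at least 2-fold lower and 1, Tcf7, higher, at a median of -0.96 (-1.22 to -0.65). EGFR family ligands had 2 of 5 members lower, with Nrg1 at 67.7 and 33.5 CPM. The LIF and STAT3 list had all 12 members within 2-fold, at a median of -0.38, and the LIF and STAT3 axis in epithelium was -0.25 when scaled by the median of ratios.

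By size alone, the epithelial genes most above the control were led by Clca1, a secreted protein of mucous cells, at 1.43 and 643 CPM, 450.4-fold higher (273 to 805). Golm1 was 19.8-fold (15.5 to 25.6), Asic2, a proton-gated channel, 15.4-fold, Prap1, an abundant secreted protein of the pregnant uterus, 9.99-fold (1277 and 12762 CPM), and Uox 8.35-fold higher. Csgalnact1, Lrg1, Mfsd4a, Klk1 and Spp1 (osteopontin) were between 5.14-fold and 7.45-fold higher. Those most below the control were the noncoding Far2os2 at 42.2-fold and Far2os1 at 22.6-fold, then Hdc, Calb1, Il17rb at 18.0-fold, Acot7 at 17.7-fold, Acod1 at 17.3-fold, Slc2a12, a glucose transporter, at 17.1-fold, Ovgp1 at 16.9-fold and Mme, neprilysin, at 15.6-fold lower. In luminal cells alone the leading genes were Clca1, Golm1 and Asic2 above the control and Aspg, Far2os2 and Hdc below it, with Aspg 133-fold lower (60.6 to 364) on 6 UMIs.

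**Figure D3:**
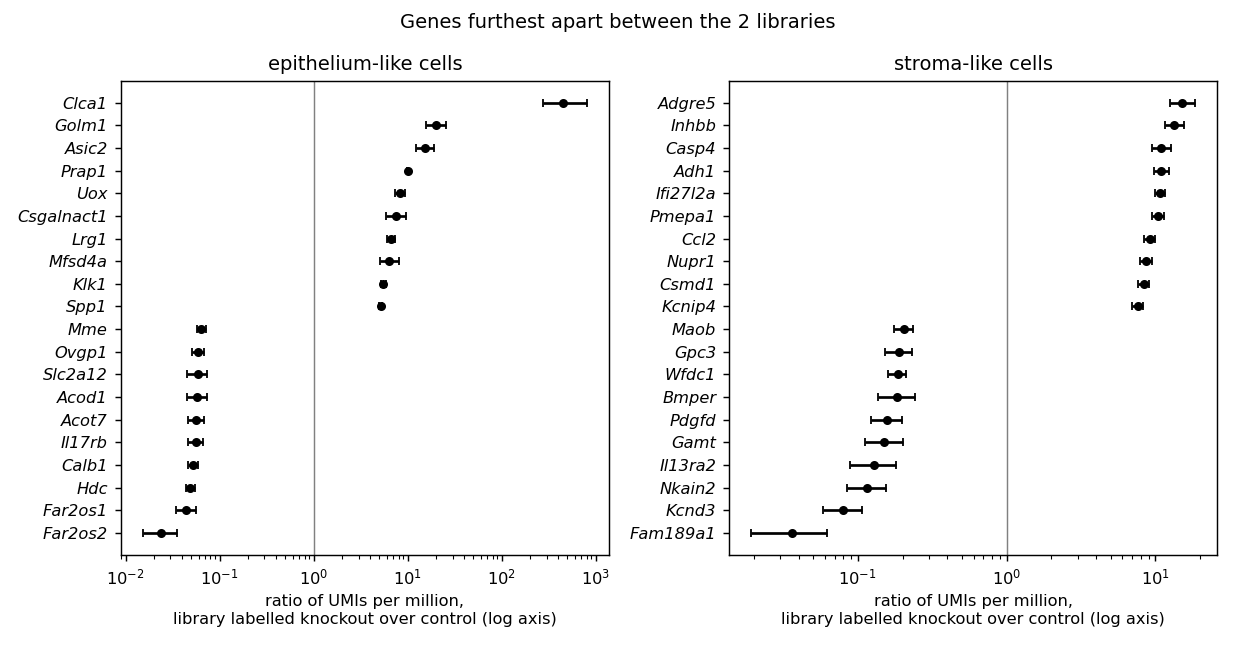
Ratio of CPM in the library labelled knockout over the control (horizontal axes, log scale) for the genes singled out by size (vertical axes) in epithelium (left) and stroma (right), as points with exact 95% intervals. Among the genes drawn, Clca1 in epithelium lay farthest above 1, at a 450.4-fold higher level, and Far2os2 in epithelium farthest below, at a 42.2-fold lower level.

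In stroma, the comparison asked whether the Hedgehog and progesterone response downstream of epithelial Ihh, growth factor output and decidual genes differ. Ptch1, the Hedgehog receptor and target, was 126 and 53.4 CPM, 2.36-fold lower (2.06 to 2.72), and Hhip, a Hedgehog-binding inhibitor, 4.58-fold lower (2.53 to 9.25). Fkbp5, a steroid receptor target, was 3.16-fold lower (2.49 to 4.06). Hand2, the stromal factor that restrains epithelial growth under progesterone, was 95.8 and 67.7 CPM, and Nr2f2 441 and 281 CPM, both within 2-fold. Of 18 members of the stromal progesterone and Hedgehog list, 4 were at least 2-fold lower, 3 higher (Wnt4 and Bmp2 among them) and 11 within 2-fold, at a median of -0.32 (-0.39 to -0.25) and percentile 0.08.

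ERK feedback genes were higher in stroma of the library labelled knockout. Spry4 was 6.24-fold higher (3.62 to 10.7) and Spry1 5.91-fold (3.48 to 9.95), both inhibitors of receptor tyrosine kinase signalling, Fosl1 3.88-fold (2.84 to 5.27) and Egr1, an immediate early gene, 2.88-fold (2.73 to 3.05). Of 15 measured members, 9 were at least 2-fold higher and 0 lower, at a median of 1.03 (0.90 to 1.32) and percentile 100. Errfi1 was itself higher there, as given above. Nrg1, an ERBB ligand, was 103 and 622 CPM, 6.07-fold higher (5.76 to 6.40), one of 2 higher members among 5 measured EGFR family ligands. That list's median of -0.17 (-0.76 to 1.00) had no settled sign, and the EGFR family ligands in stroma were 0.46 by means over cells. The dissociation stress list had a median of 0.58 (0.50 to 0.61) in stroma, at percentile 99.99. Of its 17 members 16 were higher there, 1 of them, Egr1, by at least 2-fold. Whether a response to dissociation raised the ERK feedback genes, or the stromal chemokine genes given below, was not tested.

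Cell cycle genes were lower in stroma as well, with Mcm2, part of the replicative helicase, at 19.6 and 2.67 CPM, 7.36-fold lower (4.08 to 14.8), and Top2a 6.31-fold lower (3.50 to 12.7). Mki67 was 6.47 and 3.40 CPM, on 14 UMIs in the library labelled knockout. Of 26 members, 17 were at least 2-fold lower, 0 higher and 9 within 2-fold, at a median of -1.30 (-1.78 to -1.13) and percentile 0. The pooled background cells had a cell cycle median of -0.67 (-0.93 to -0.50), also at percentile 0. Of 24 members measured there, 7 were at least 2-fold lower and 0 at least 2-fold higher. A difference across the whole library is therefore not excluded as a part of the lower cell cycle levels.

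Decidual genes of the stroma were mostly level or higher. Wnt4, a decidual WNT ligand, was 7.52 and 37.9 CPM, 5.03-fold higher (4.07 to 6.21), and Bmp2, required for decidualization, 24.3 and 60.0 CPM, 2.47-fold higher (2.13 to 2.86). Alpl, alkaline phosphatase, was 13.8-fold higher (6.96 to 28.4). The decidualization list had 5 of 15 measured members at least 2-fold higher, 1 lower and 9 within 2-fold, at a median of 0.59 (0.53 to 0.65), and decidualization in stroma was 0.33 with members of at least 100 UMIs. Matrix genes had 6 of 21 members higher, such as Lox, which crosslinks collagen, 4.15-fold (3.49 to 4.93) and Tnc 3.61-fold (2.72 to 4.76), 1 lower, Col14a1, and 14 within 2-fold. Their median was 0.10, and the extracellular matrix in stroma ranged from 0.026 by means over cells to 0.18 with free RNA subtracted. WNT genes went both ways in stroma, with 6 of 14 higher, 2 lower and a median of -0.03, but the WNT pathway in stroma was 1.09 with members of at least 1 UMI. Epithelial RNA was counted in stroma of both libraries, and 10 of 11 epithelial markers had higher levels in the library labelled knockout, from 3.17-fold for Cldn7 to 6.42-fold for Krt7, with Wfdc2 at 8.24 and 42.0 CPM. The interval of Cldn4 (0.783 to 31.6) included a ratio of 1. The remaining marker, Cldn3, was 42.7 and 1.94 CPM, so the sums of all 11, 61.1 and 90.8 CPM, hide that difference.

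Interferon and chemokine genes were higher in stroma of the library labelled knockout. Ifi27l2a was 31.8 and 342 CPM, 10.7-fold higher (9.87 to 11.7), Ifit1 8.60-fold (5.32 to 14.0), Isg15 5.09-fold (3.85 to 6.70) and Bst2, a viral tethering factor, 4.85-fold (4.52 to 5.20). Of 14 measured interferon list members, 11 were at least 2-fold higher and 0 lower, at a median of 1.67 (1.44 to 2.05) and percentile 100. In epithelium the same list had 3 members higher and 4 lower, with Isg15 3.60-fold lower (2.98 to 4.38) and Bst2 2.88-fold lower (2.70 to 3.08), at a median of -0.27 (-0.44 to -0.12) and percentile 29.8, within the range of matched random lists. The interferon response in epithelium was -0.14 when scaled by the median of ratios and -0.11 in thinned cells. Ccl2, which recruits monocytes, was 9.15-fold higher (8.36 to 10.0) in stroma, Cxcl2, a neutrophil attractant, 11.9-fold (9.67 to 14.8) and Cxcl1 5.90-fold (5.38 to 6.47). The chemokine and cytokine list had 9 of 14 members higher in stroma (median 1.73, 1.46 to 1.90) and 6 of 11 in epithelium (median 1.17, 1.01 to 1.32), where Cxcl1 was 4.04-fold and Cxcl2 4.70-fold higher. The pooled background cells had a chemokine median of 0.57 (0.30 to 0.69), at percentile 99.95. A difference across the library is therefore not excluded as a part of the higher chemokine levels. Free RNA is not excluded as a part of Cxcl1 and Cxcl2 in stroma. Ccl2 was 269 CPM in stroma of the library labelled knockout, and at most 9.86 CPM in its other classes of at least 50 cells. For chemokines and cytokines in epithelium the median depended on the UMI minimum of members, at 0.34 with 1 UMI and 1.90 with 100 UMIs.

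By size alone, the stromal genes most above the control were Adgre5, an adhesion receptor, at 15.2-fold (12.5 to 18.5), Inhbb, an inhibin and activin subunit, at 9.53 and 128 CPM and 13.4-fold (11.6 to 15.6), and the inflammatory caspase gene Casp4 at 11.0-fold higher. Adh1, Ifi27l2a, Pmepa1, a brake on TGF-beta signalling, Ccl2, Nupr1, Csmd1 and Kcnip4 lay between 7.61-fold and 10.9-fold higher. Those most below it were Fam189a1 at 27.7-fold (16.2 to 52.1), the potassium channel gene Kcnd3 at 12.5-fold, Nkain2 at 8.69-fold, and Il13ra2, a decoy receptor for interleukin 13, at 7.73-fold lower. Gamt, Pdgfd, a growth factor, Bmper, Wfdc1, Gpc3 and Maob lay between 4.92-fold and 6.63-fold lower. In the library labelled knockout Adgre5 and Casp4 were 79.1 and 107 CPM in stroma, but 214 and 209 CPM in another class. Stromal sums can also mix makeup with expression. Cluster 13 held 43 of 1113 stromal cells labelled knockout and 22 of 3188 in the control. With no doublets removed, Adh1 was among the leading genes of a cluster with mostly the same leading genes.

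**Figure D4:**
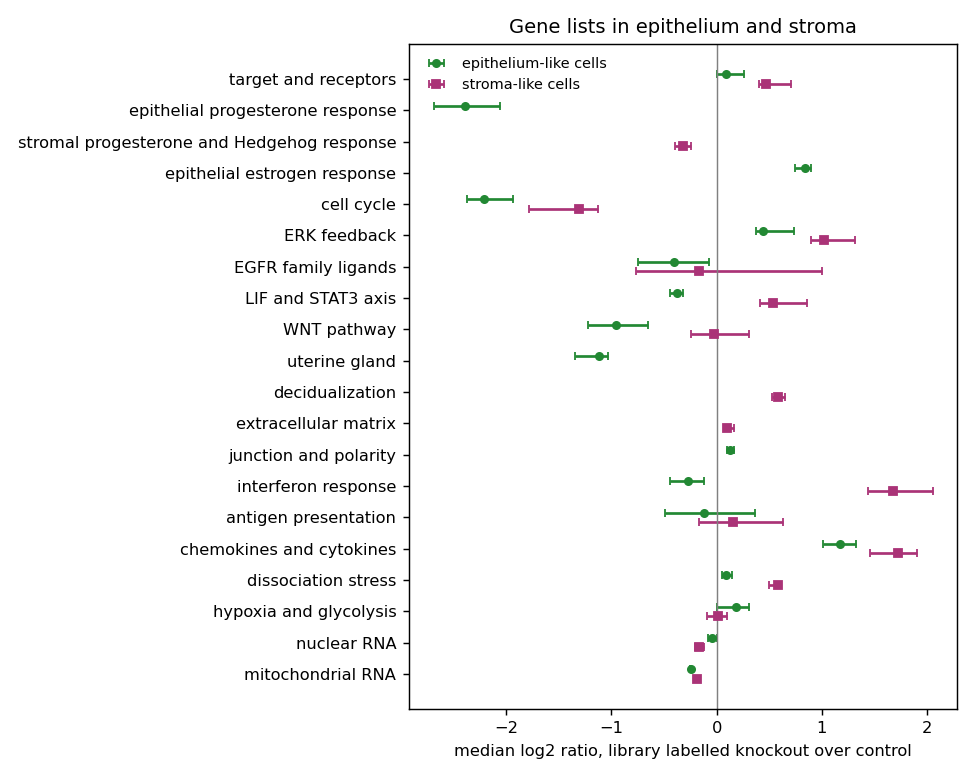
Median log2 ratio of the library labelled knockout over the control (horizontal axis) per gene list (vertical axis), as circles for epithelium and squares for stroma with 95% intervals from Poisson redraws. The epithelial progesterone list lay at -2.39 and the cell cycle list at -2.21 in epithelium, while the chemokine list at 1.73 and the interferon list at 1.67 in stroma lay above 0.

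NK-like cells numbered 100 in the control and 163 in the library labelled knockout, with median UMIs of 5879 and 1479. Il5, a cytokine of type 2 lymphocytes, had 0 UMIs in the control and 34 in the library labelled knockout (112 CPM). Its ratio was 23.3 when computed against the floor of 3 counts, and the exact lower bound of the ratio was 17.9. Ifi27l2a was 6.06-fold higher (3.64 to 10.5) and Camkmt 7.39-fold (3.59 to 16.7). Ifi27l2a was 204 CPM there and 342 CPM in stroma of the library labelled knockout, so free RNA is not excluded as a partial source. Below the control were Fdps, an enzyme of sterol synthesis, 9.86-fold (3.71 to 37.1), Nme1 3.61-fold (2.62 to 5.09), and Pole, a DNA polymerase subunit, 17.0-fold (2.87 to 692) on 1 UMI.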

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

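The tests of free RNA, swapped labels and a response to dissociation for Errfi1 were chosen only after the result was seen, and the other tests in this part before it. Differences of effect between epithelium and stroma were not tested, since each group had 1 library. Errfi1 had a ratio of the library labelled knockout over the control of 0.896 in epithelium and 3.85 in stroma, on opposite sides of 1. The epithelial value is close to the class-wide shift, and scaled by the median of ratios the log2 ratio of Errfi1 in epithelium was -0.025. The interferon response list had a median log2 ratio of -0.27 in epithelium, at percentile 29.8 of matched random lists (-0.11 for the interferon response in epithelium in thinned cells), and 1.67 in stroma, at percentile 100. The LIF and STAT3 list was at -0.38 in epithelium, with all 12 measured members within 2-fold, and at 0.54 in stroma, where Il6, Il11, Lif and Msx1 were higher at low counts. With free RNA subtracted, the LIF and STAT3 axis in stroma was 1.09. Among classes with too few cells for a gene by gene comparison, Errfi1 had a ratio of 3.06 (2.17 to 4.29) in smooth muscle, 2.84 (2.09 to 3.85) in pericytes, 4.50 (1.47 to 16.3) in plasma-like cells, 1.51 (0.870 to 2.53) in endothelium and 0.669 (0.272 to 1.44) in macrophages.

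Stromal and luminal cells of the libraries lay in separate clusters, while glandular, endothelial and immune cells of both libraries shared clusters. A technical difference across the whole library was argued against as the whole cause. The 87 genes 2-fold apart in the same direction in stroma and luminal cells had signed median log2 ratios of 2.30 and 2.46 there. In the pooled background cells their median was 0.50 (0.43 to 0.69). The genes were picked for their size in stroma and luminal cells, which raises the medians there. The pooled median lay above 0, so a difference across the library is not excluded as a part of the cause. Depth was argued against as the whole cause, because after thinning to equal UMIs 90.5% of stromal and luminal cells still lay in clusters with at least 90% of their cells from 1 library, against 91.5% before. The share went from 88.7% to 98.5% in stroma but from 98.1% to 72.2% in luminal cells, so a part of the luminal separation stays open to depth. A difference by genotype, by animal or by hormonal state on the day of collection stays open and was not tested.

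Errfi1 was higher in stroma of the library labelled knockout, against its label. Free RNA was argued against, since its stromal level of 745 CPM (719 to 772) lay above the 548 CPM over all cells of that library. Swapped labels cannot be told apart from a deletion outside the counted tags. The luminal ratio was 0.955 (0.922 to 0.989) and the glandular ratio 0.635 (0.575 to 0.700), so neither was higher in the library labelled knockout. These ratios decide only if the counted tags lie in the deleted part, which is not given in the sources used here. A response to dissociation stays open as well. The dissociation stress list had a median log2 ratio of 0.58 in stroma, above 0, with 16 of 17 members higher and 1 at least 2-fold higher. Transcription of a floxed gene whose product no longer acts, incomplete deletion, and differences between animals were not tested.

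The interferon list stood above matched random lists in stroma. A difference across the library was argued against as the whole cause, as the list's median in the pooled background cells was 0.13 (-0.17 to 0.45). That lay under the bound of 0.84 set from stroma. Of 14 members measured in the pool 1 was at least 2-fold higher, but in NK-like cells alone Ifi27l2a was 6.06-fold higher (3.64 to 10.5). Its level in the library labelled knockout was 204 CPM in NK-like cells and 342 CPM in stroma. Free RNA was argued against, as 7 of the 11 members at least 2-fold higher had stromal levels above the level over all cells of that library, and 2 lay below it. Depth was argued against, as the median over thinned stromal cells was 1.67. The pattern may be biological, as a hypothesis found and tested on the same libraries, and genotype, infection status and hormonal state of the animals stay open and untested.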

How the results depend on the processing

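Luminal or glandular cells alone and clusters made without marker and gland genes were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each group had 1 library. Of 120 alternative values for the 12 main results, 103 stayed within their counting interval, 15 moved with the same direction and 2 reversed; for all of them the cause was not tested, except where fewer members were counted. The share differences were kept under every alternative run, with the epithelial share at 32.6 to 33.2 points, the stromal share at -36.7 to -35.1 and the immune share at 3.27 to 4.15. Values below are log2 ratios or list medians. Scaling by the median of ratios gave -0.025 for Errfi1 in epithelium and 0.97 for the estrogen list. Means over cells gave Errfi1 -0.23 in epithelium and 2.05 in stroma, and subtracted free RNA -0.24 and 2.07. Thinned cells gave -0.24 for Errfi1, -1.44 for the cell cycle and 0.33 for ERK feedback in epithelium. Members with at least 100 UMIs gave -1.83 for the epithelial cell cycle, and those with at least 1 UMI -2.01 for the epithelial progesterone response in epithelium. Luminal cells alone gave -0.067 for Errfi1. Glandular cells alone gave -0.66 for Errfi1, -0.27 for progesterone, 2.23 for estrogen (0.78 for the epithelial estrogen response in glandular epithelium with members of at least 100 UMIs, 1.08 with at least 1 UMI), and reversed the cell cycle to 0.27 and ERK feedback to -0.078, both with intervals that include 0. Of 646 alternative values for 59 other list results, 559 were the same, 84 moved and 3 reversed: the gland list in luminal cells at -0.62 with free RNA subtracted and -0.27 with members of at least 1 UMI, and hypoxia in glandular cells at 0.036 when thinned. Reversed counts only results whose own interval excluded 0, so lists near 0, such as antigen presentation, WNT in stroma and nuclear RNA, changed sign in some settings without being counted. Of 2812 for 313 gene results, 2459 were the same, 344 moved and 9 reversed. These were Tgfa when thinned (0.55 in epithelium, 0.46 in luminal cells), H2-D1 in thinned glandular cells (-0.030), Hbegf in luminal cells by median of ratios (0.014), Cd74 in luminal cells and Adm in stroma with free RNA subtracted (-0.79 and -0.40), and Xist in epithelium by median of ratios (0.051), means over cells (0.012) and free RNA (0.071). No value was given for genes at 0 in a library whose floor lay above the other library's level. Depth limits low genes in the library labelled knockout, which held 4119197 UMIs in stroma, 1246842 in glandular and 304180 in NK-like cells.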

Other observations

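Tight junction and polarity genes of the epithelium were mostly level, with 14 of 16 members within 2-fold (median log2 ratio 0.13), apart from Cldn1, 5.13-fold lower (3.98 to 6.69) in the library labelled knockout, and Cldn3, at 1031 and 295 CPM. The class I genes B2m and H2-K1 were higher in both compartments, 2.17-fold (2.03 to 2.31) and 2.21-fold (2.11 to 2.31) in epithelium, and 2.16-fold (2.02 to 2.32) and 2.24-fold (2.10 to 2.38) in stroma. The whole antigen presentation list, which also holds class II genes, had medians of -0.12 over 9 members in epithelium and 0.16 over 11 in stroma. These medians have no settled direction: antigen presentation in epithelium was 0.61 with members of at least 1 UMI and -0.62 with free RNA subtracted, and antigen presentation in stroma was 1.12 with free RNA subtracted. Of 14 hypoxia and glycolysis genes in epithelium, 2 were higher, Egln3 by 6.65-fold (4.94 to 9.13) and Hk2, a hexokinase, by 2.78-fold (2.47 to 3.13), and 2 were lower, Ndrg1 and Bnip3, at a list median of 0.19. In stroma Egln3 and Hk2 were the 2 higher members of 13, at a median of 0.01.

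The gland list over all epithelium had 6 of 12 members lower, at a median of -1.12 (-1.35 to -1.03) and for the uterine gland in epithelium -0.59 with members of at least 100 UMIs, with 5.43 luminal cells per glandular cell in the control and 8.42 in the library labelled knockout. Interferon genes of the pooled background cells were mostly within 2-fold, with 1 of 14 higher. Nuclear RNA had medians of -0.04 in epithelium and -0.16 in stroma, where Neat1 was 2.48-fold higher (2.38 to 2.59) and Meg3, an imprinted noncoding gene, 2.87-fold lower (2.63 to 3.13). Mitochondrial RNA had medians of -0.25 in epithelium and -0.19 in stroma, with all 11 members within 2-fold in each, and 0.40 in glandular cells. In glandular cells, where gland genes were lower, 10 of the 11 members were higher, at percentile 99.955. Their median mitochondrial share was 3.33% in the control and 4.15% in the library labelled knockout. The dissociation stress list had a median of 0.09 in epithelium, with all 17 members within 2-fold. Scaled by the median of ratios, the small epithelial medians were 0.26 for junction and polarity in epithelium, 0.32 for hypoxia and glycolysis in epithelium, 0.22 for dissociation stress in epithelium, 0.091 for nuclear RNA in epithelium and -0.11 for mitochondrial RNA in epithelium. In epithelium, 13 stromal marker genes summed to 287 and 484 CPM, mostly Fbln1 at 263 and 469 CPM. Other stromal markers there went against that sum, with Dcn at 3.43 and 0.818 CPM, Col3a1 at 4.19 and 1.05 CPM and Vcan at 5.43 and 1.11 CPM, while Col6a3 was 1.43 and 9.76 CPM.

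UMIs per cell differed between the libraries by class. Median UMIs per luminal cell were 12107 in the control and 9797 in the library labelled knockout, a ratio of 0.809, while ratios of the other named classes lay between 0.252 in NK-like and 0.579 in glandular cells. In stroma the medians were 8952 and 3595.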
